A study of Mus musculus with 96 samples.

How the data were processed

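Bulk RNA sequencing was used to profile the prefrontal cortex (PFC) and the nucleus accumbens (NAc) of 48 mice of the FCG model. In it the testis-determining gene Sry has been removed from the Y chromosome (written Y-) and added to an autosome as a transgene, so that chromosomes and gonads vary independently. Per the labels' protocols, RNA was extracted from tissue punches with the Qiagen miRNeasy Micro kit, and libraries of polyadenylated RNA were made with the Illumina TruSeq mRNA kit from 100 ng of RNA and 15 cycles of amplification. They were sequenced on an Illumina NextSeq instrument as paired reads of 50 bp, with about 45 M reads per sample stated. Per the submitters' processing notes, FastQC 0.11.9, Trimmomatic 0.38, HISAT2 2.2.0, edgeR and DESeq2 were used with the mouse build GRCm38 (mm10), with no roles stated. The counting tool, its strand setting, the gene annotation and the filter on genes are not given in the sources used here.

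The deposited values are raw counts, 1 table per region with the same 19918 Ensembl genes in both and 1 column per library. Column names matched the library names in the labels for each of the 96 libraries, and no per-sample column was left unused (0 columns). Gene symbols and coordinates came from the GENCODE M21 annotation of GRCm38, in which 19795 of the gene IDs were found and 123 were not. In it 12 symbols belonged to more than 1 ID. Because strand use is not stated, values of genes that overlap another measured gene on the opposite strand (5332 of 19795) are uncertain. Of the genes named, these are Xist, Jpx, Ftx, Utp14a, Hccs, Arhgap6, Mid1, Irf7, Cxcl10, H2-Q4, Gm13091, Rab10os, Rps4l, Atp6v1g2, Htra1, Rilpl1, Acat3, B230110C06Rik, Veph1, Myom1, Rangrf, 4930470G03Rik, Penk, Ppp1r1b, Nrn1, Gad1, Zic1, Zic4 and G530011O06Rik. Genes of families whose members share sequence are uncertain as well.

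Total counts per library ran from 67.6 to 104.4 M in the PFC (mean 83.0 ± 8.48 SD, n = 48) and from 45.9 to 120.8 M in the NAc (75.4 ± 12.6 SD, n = 48). These totals lie above the stated read number. Floors given for a count of 0 use 3 counts over a group and, like any value from reads without molecular identifiers, cover counting error only. Across all 121 pairs of libraries of the same group per region, the chi-square statistic per degree of freedom was at least 7.58 in the PFC and 16.9 in the NAc, so no pair of libraries had the same counts within sampling noise.

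Groups came from the genotype and treatment in the labels, and the batch label gave 3 cohorts. The labels name a different animal for each library of a region, so n counts animals. In each region the counts were tested with edgeR 4.0.16 (quasi-likelihood fit with robust dispersion, TMM scaling, filterByExpr by group) in R 4.3.3, with 8 group means and the cohort in the model. That left 19292 genes in the PFC and 19684 in the NAc. Contrasts weighted groups equally: stress minus control, XX minus XY, testes minus ovaries, stress within each genotype, the 3 interactions between these factors, and the cohort terms. Adjusted p-values are Benjamini-Hochberg values over the genes of a region, and genes below 0.05 are called changed. Levels are CPM, counts scaled to a common library size, computed here with TMM library sizes, as mean ± SD over libraries, except for Y-linked genes and Xist, which use plain library totals.

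Both regions came from the same animals, as the animal number in the titles shows, so the regions were compared in 1 edgeR fit over 96 libraries and 19918 genes with the animal as a replicate block and the cohort within region. The pairing was also looked for in the values: the median correlation of an animal's PFC and NAc deviations from their group means over 12336 genes was 0.0895, 22 of 48 animals were above 0.1, and 9 correlated best with their own number.

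Before the data were examined, 29 gene lists were fixed, covering sex-linked genes, stress-related pathways, receptors and markers of brain cell types. Each was tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation, and with fry, which asks whether the members move one way on balance. A list score is the mean log2 CPM of its members in a library, and differences of scores were tested by two-sided permutation of 100000 draws, or of all draws where a group had fewer than 10 values, in scipy 1.17.1. The genes named in the text follow a rule fixed at the same time. For stress, chromosomes and gonads these are the called genes with the 10 highest and 10 lowest log2 fold changes, a mean of at least 0 log2 CPM and a symbol that is not a predicted-gene name. Where fewer than 5 passed, the 5 genes with the smallest p are given as values. For interactions and for stress within a genotype, 2 such genes are given as values where none was called, and otherwise the called genes with the smallest p. All members of the sex-linked lists and up to 4 members of another list described are also named. The rule covers the region markers as well. Of the region markers, 1 is not reported here. Of the others the text names a part, and gives the rest as counts and medians. Genes outside this rule are said to have been chosen after their values were seen.

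The scripts were tested on simulated data with 200 changed genes, drawn from the real means and library sizes. For stress over all genotypes, the test recovered 82.1% of 1.2-fold changes and 100% of 1.5-fold changes in the PFC, and 67.2% and 98.5% in the NAc. For stress within XX mice it recovered 91% of 1.5-fold changes in the PFC and 62.7% in the NAc. Alternatives fixed in advance were no cohort term, size factors of DESeq2, no filter, a stricter filter of 1 CPM in a share of 0.5 of the libraries, DESeq2 1.42.0, limma-voom with sample weights, 2 surrogate variables (sva 3.50.0), each cohort alone, and leaving out each library. Added after the data were seen were 2 marker scores as covariates, the interferon score as a covariate, 2 XY- controls left out, and region fits without each of the 5 XX control animals. Each count of genes was also computed for 100 splits of the libraries, the real one included (25 for the regions).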

Results

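RNA sequencing profiled the prefrontal cortex (PFC) and the nucleus accumbens (NAc) of 48 mice, giving 48 libraries per region. The mice belonged to the FCG model, which separates sex chromosomes from gonads. Its genotypes are XX mice with ovaries, XX mice with testes formed under an Sry transgene (XXSry), XY- mice with ovaries, and XY- mice with testes under the same transgene (XY-Sry). The Y- chromosome lacks Sry. They were controls or underwent subchronic variable stress, in which restraint lasted 1 hour per session and 3 sessions fell on alternating days over 6 days. Control and stressed animals numbered 5 and 6 for XX, 6 and 6 for XXSry, 7 and 6 for XY-, and 6 and 6 for XY-Sry, and they came from 3 cohorts. Total counts per library averaged 83.0 M (SD 8.48, range 67.6 to 104.4, n = 48) in the PFC and 75.4 M (SD 12.6, range 45.9 to 120.8, n = 48) in the NAc. The comparisons ask how stress, chromosome complement and gonads each relate to expression in these corticostriatal regions.

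Y-linked genes and Xist, the RNA that silences an X chromosome in XX cells, followed the chromosome labels in all 96 libraries. In the PFC, Xist had 1010 ± 86.6 CPM (SD, n = 23) in XX and 0.128 ± 0.178 CPM (SD, n = 25) in XY mice. In the NAc it had 1958 ± 184.5 against 0.745 ± 0.801 CPM. Of the Y-linked regulators of transcription, translation and RNA, Uty had 22.6 ± 1.91 CPM in the PFC of XY mice and no read in the 23 XX libraries. There, 3 counts over the group would be 0.00160 CPM. Uba1y, a ubiquitin-activating enzyme gene, had 0.168 ± 0.0999 CPM in the PFC and 0.379 ± 0.158 CPM in the NAc of XY mice. Its count was 0 in XX mice in both regions. The helicase gene Ddx3y had 70.3 ± 4.84 CPM in the PFC of XY mice against 13 counts in all XX libraries together. The translation factor gene Eif2s3y had 50.8 ± 7.21 CPM against 7 counts, and the histone demethylase gene Kdm5d 36.6 ± 1.89 CPM against 14 counts. In the NAc, the XY means of Uty, Ddx3y, Eif2s3y and Kdm5d were 30.1 ± 2.64, 81.2 ± 7.13, 76.6 ± 11.8 and 62.6 ± 5.18 CPM. They stood against 28, 41, 104 and 43 counts over the XX libraries. All 5 measured Y-linked genes passed the test in each region, and adjusted over the list alone the count was also 5. Sry itself was not among the genes tested.

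Chromosome complement, compared as XX minus XY over both gonad types, was marked by a block of genes at the distal end of the X chromosome that were lower in XX mice. The Y- chromosome of this model has been reported to carry a translocated piece of the X chromosome. All 7 measured genes on the list of that piece fell in XX in both regions. In the PFC, Tlr7 (ENSMUSG00000044583, X 167304929 to 167330558 in GRCm38), an endosomal receptor for single-stranded RNA, had 4.04 ± 0.516 CPM in XX (SD, n = 23) and 8.98 ± 1.32 CPM in XY mice (SD, n = 25). Its log2 fold change was -1.15 (SE 0.0535, edgeR adjusted p = 5.23e-23). Prps2, an enzyme of nucleotide synthesis, had 37.5 ± 2.2 against 76.0 ± 4.64 CPM (log2 fold change -1.01, SE 0.0239). Msl3, part of a histone acetyltransferase complex, had 20.5 ± 1.26 against 41.2 ± 1.42 CPM (-1.01, SE 0.0221). Frmpd4, a scaffold protein of dendritic spines, had 145 ± 5.63 against 284.5 ± 16.3 CPM (-0.98, SE 0.0215). Tmsb4x, which binds actin monomers, differed by -0.78 (SE 0.0262). Hccs, which attaches heme to cytochrome c, and Arhgap6 differed by -0.98 (SE 0.0278) and -0.97 (SE 0.0516). These 2 genes overlap each other, so their separate values are uncertain. NAc log2 fold changes were -1.23 for Tlr7 (SE 0.0930), -1.06 for Msl3 (SE 0.0405), -1.02 for Frmpd4 (SE 0.0438), and -0.92 for Tmsb4x (SE 0.0519). They were -0.99 for Hccs (SE 0.0338), -0.99 for Arhgap6 (SE 0.0766) and -1.01 for Prps2 (SE 0.0475).

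The list of the reported translocation had a median log2 fold change of -0.98 in the PFC, and all 7 members also passed adjusted over the list alone. Its camera call held with an estimated correlation in both regions (adjusted p = 4.47e-18 in the PFC and 5.19e-16 in the NAc). Between X 167207093 and 170019281, 11 of 13 tested genes were called lower in XX in the PFC (median of all 13 -0.97) and 12 of 14 in the NAc (median -0.99). Over the rest of the X chromosome, 2 of 680 tested genes were lower and 9 higher in the PFC, and 1 of 694 lower and 8 higher in the NAc. Mid1, a microtubule-associated ubiquitin ligase gene at X 169685199 to 170005736, fell by 0.64 in the PFC (SE 0.0665, edgeR adjusted p = 1.01e-09) and by 0.67 in the NAc (SE 0.0955). It overlaps G530011O06Rik on the opposite strand, so its value is uncertain.

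**Figure D1:**
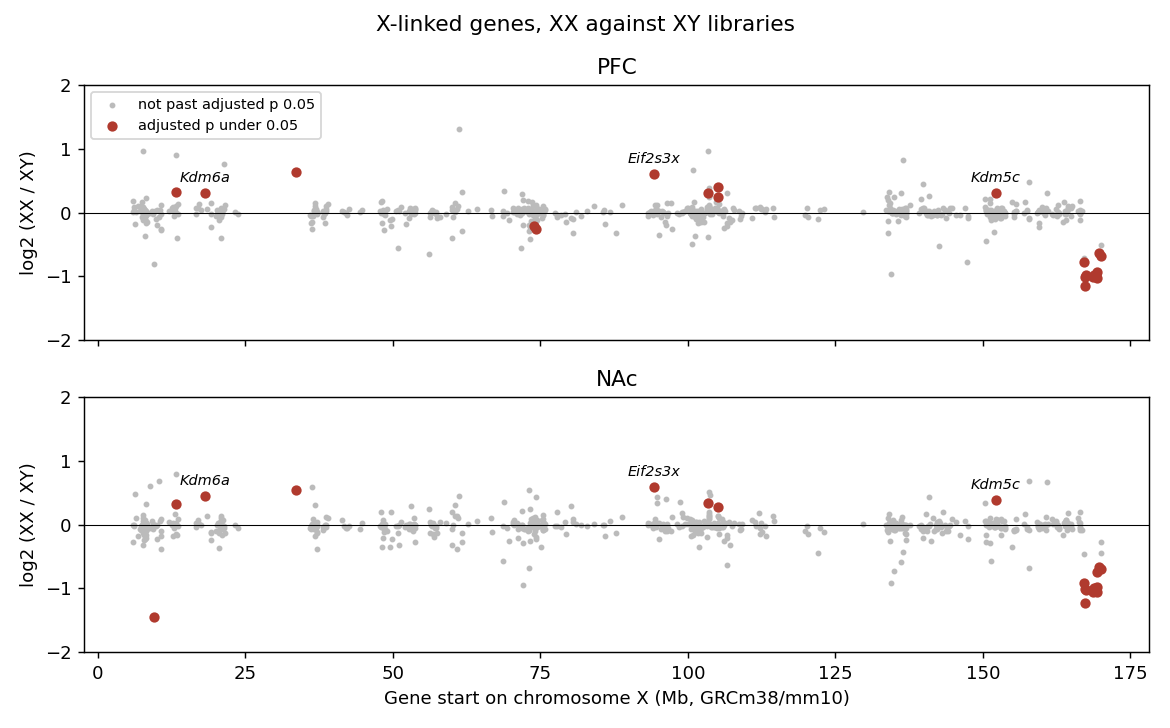
Each point is a gene of the X chromosome, placed by its GRCm38 start in megabases, with the log2 fold change of XX over XY mice on the vertical axis for the PFC and the NAc, with genes past an adjusted p of 0.05 in red and Xist not drawn. The called genes of the distal end have medians near -1, while Kdm6a, Eif2s3x and Kdm5c lie above 0.

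Genes known to escape X inactivation were higher in XX mice. In the PFC, Eif2s3x, the X-linked translation factor paralog of Eif2s3y, had 55.6 ± 2.55 CPM in XX (SD, n = 23) and 36.6 ± 1.96 in XY mice (SD, n = 25). Its log2 fold change was 0.60 (SE 0.0216, edgeR adjusted p = 6.54e-28). Kdm6a and Kdm5c, histone demethylase genes, rose by 0.31 each (SE 0.0195 and 0.0213), and the RNA helicase gene Ddx3x by 0.32 (SE 0.0215). The NAc values of Eif2s3x, Kdm6a, Kdm5c and Ddx3x were 0.59 (SE 0.0373), 0.45 (SE 0.0335), 0.39 (SE 0.0303) and 0.32 (SE 0.0395). Counting Xist and Mid1, 8 of 12 measured members were called higher and 1 lower in the PFC, and 7 higher and 1 lower in the NAc. Adjusted over the list alone, 9 were higher and 1 lower in each region. The camera call held with an estimated correlation (adjusted p = 9.04e-16 in the PFC and 2.95e-09 in the NAc). Jpx, an RNA that activates Xist, was 0.30 (SE 0.0472) higher in the PFC and 0.34 (SE 0.0534) in the NAc, and 5530601H04Rik 0.40 (SE 0.0319) and 0.27 (SE 0.0393). Both overlap or adjoin other transcripts and are uncertain without strand information. Pbdc1 rose by 0.24 (SE 0.0264) in the PFC and stood at 0.14 in the NAc (edgeR adjusted p = 0.206). Ftx, Utp14a and Car5b did not pass, with values of 0.10, 0.04 and -0.03 in the PFC and 0.11, 0.02 and 0.04 in the NAc.

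Interferon-response genes, which cells switch on through interferon receptors, were lower in XX than in XY mice. All 20 measured members of the list lay below 0 in each region. Of these, 12 were called lower in the PFC and 15 in the NAc, and adjusted over the list alone 19 and 20. In the PFC, Rsad2, an antiviral enzyme gene, had 1.87 ± 0.506 CPM in XX (SD, n = 23) and 3.05 ± 1.15 in XY mice (SD, n = 25). Its log2 fold change was -0.74 (SE 0.112, edgeR adjusted p = 3.16e-05). Irf7, a transcription factor of the interferon response, fell by 0.87 (SE 0.168), Oasl2 by 0.86 (SE 0.179) and Ifitm3, a barrier to virus entry, by 0.57 (SE 0.108). In the NAc, Ifit1, which binds foreign RNA, had 2.42 ± 1.33 CPM in XX and 8.71 ± 7.74 in XY mice (log2 fold change -1.67, SE 0.281, edgeR adjusted p = 0.000363). Oasl2 had 4.43 ± 3.08 against 16.4 ± 17.7 CPM (-1.65, SE 0.317). Usp18, which removes the ubiquitin-like protein ISG15 from its targets, fell by 1.60 (SE 0.273). Ifi44 fell by 1.46 (SE 0.280), Isg15 by 1.31 (SE 0.264), Irf7 by 1.31 (SE 0.273), Ifit3 by 1.07 (SE 0.189) and Rsad2 by 0.92 (SE 0.172).

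The median of the interferon list was -0.51 in the PFC (camera adjusted p = 2.43e-27; adjusted p = 0.0156 with an estimated correlation; fry adjusted p = 0.000531). It was -0.87 in the NAc (camera adjusted p = 1.25e-46; adjusted p = 0.00192 with an estimated correlation; fry adjusted p = 0.000205). The interferon score, the mean log2 CPM of the list in a library, was 1.66 ± 0.151 in XX and 2.10 ± 0.429 in XY mice in the PFC (SD, n = 23 and 25). The difference was -0.43 (two-sided permutation p = 2e-05, the smallest that the draws can give; adjusted p = 0.00024 over 24 such tests). Within cohorts 1, 2 and 3 the PFC differences were -0.50, -0.35 and -0.41 (exact permutation p = 5e-06, 0.0328 and 0.12). NAc scores were 1.72 ± 0.312 in XX and 2.52 ± 0.797 in XY mice, a difference of -0.80 (permutation p = 4e-05, adjusted p = 0.00032). It was -0.88, -0.79 and -0.76 within the 3 cohorts (exact permutation p = 0.000321, 0.111 and 0.0392). By genotype the NAc means were 1.84 ± 0.412 for XX (n = 11), 1.60 ± 0.101 for XXSry (n = 12), 2.91 ± 0.738 for XY- (n = 13) and 2.09 ± 0.637 for XY-Sry (n = 12). Microglial markers had medians of -0.11 in the PFC (12 of 14 below 0) and -0.08 in the NAc (11 of 14). These camera calls were lost with an estimated correlation (adjusted p = 0.262 and 0.569). The chemokine gene Cxcl10 and Itgax, an integrin of myeloid cells, chosen after their values were seen, also fell in both regions, by 2.12 (SE 0.511) and 1.29 (SE 0.270) in the PFC.

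**Figure D2:**
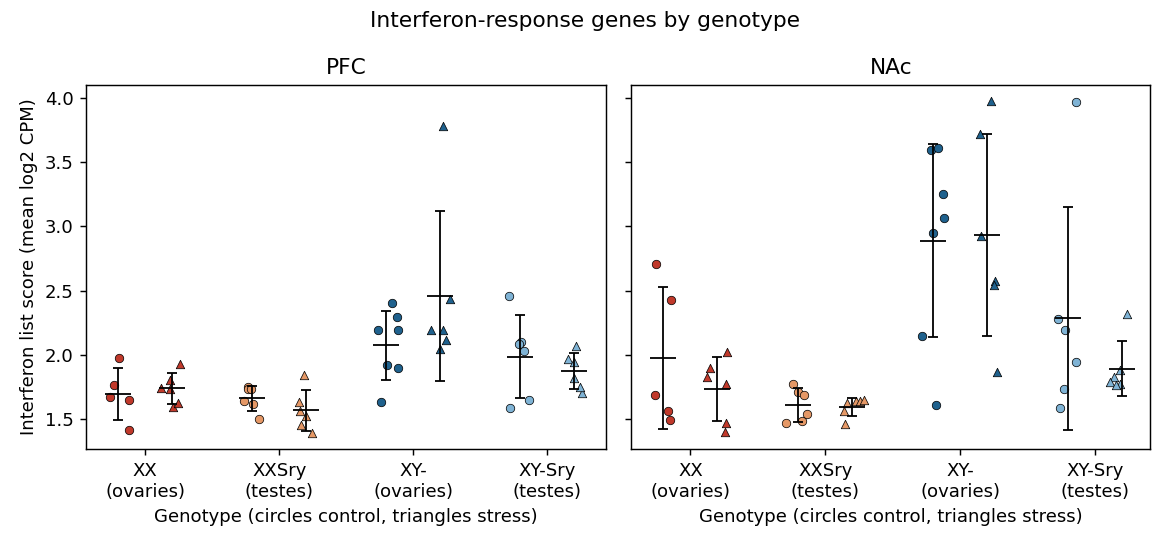
Interferon score (mean log2 CPM of 20 genes) of each library by genotype in the PFC and the NAc, with circles for controls, triangles for stressed mice, and mean ± SD. XY- mice have the highest mean in both regions, at 2.25 in the PFC and 2.91 in the NAc.

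Outside the sex chromosomes, single genes also differed between chromosome complements. Actb (ENSMUSG00000029580), cytoplasmic beta-actin, chosen after its values were seen, had 722.6 ± 21.7 CPM in XX (SD, n = 23) and 825 ± 31 in XY mice (SD, n = 25) in the PFC. It fell by 0.18 there (SE 0.0167, edgeR adjusted p = 1.36e-11) and by 0.13 in the NAc (SE 0.0265, edgeR adjusted p = 0.00559). Actg1, gamma-actin, so chosen too, fell by 0.14 in the PFC (SE 0.0243) and stood at -0.08 in the NAc (edgeR adjusted p = 0.918). Cnn2, an actin-binding calponin, also so chosen, fell by 0.32 in the PFC (SE 0.0737) and 0.43 in the NAc (SE 0.0696). Markers of meninges and of blood vessels, which are rich in contractile genes, had PFC medians of -0.24 and -0.07 (adjusted p = 0.361 for each with an estimated correlation). Mlph, an adaptor of organelle transport, was higher in XX by 0.54 in the PFC (SE 0.0798) and 0.49 in the NAc (SE 0.118). In the PFC, Colq, the collagen tail of acetylcholinesterase, rose by 0.46 (SE 0.122) and Cd6, a lymphocyte surface receptor, by 0.42 (SE 0.0793). There, Myo18b, a myosin, rose by 0.31 (SE 0.0721) and Pcdhb3 by 0.31 (SE 0.0753). In the NAc, Sod3, extracellular superoxide dismutase, rose by 0.28 (SE 0.0600), Pcdhb8 by 0.29 (SE 0.0717) and the antisense transcript Rab10os by 0.21 (SE 0.0514). The clustered protocadherin genes Pcdhb3 and Pcdhb8 share sequence with their neighbours and Rab10os lies opposite another gene, so these values are uncertain.

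In all, edgeR called 217 of 19292 genes between chromosome complements in the PFC, 54 higher and 163 lower in XX. In the NAc it called 115 of 19684, 15 higher and 100 lower. Outside X and Y these were 188 (45 higher, 143 lower) and 87 (7 higher, 80 lower). Of the genes outside X and Y, 49 of 18225 tested in both regions were called in both, each in the same direction. Independent lists would share 0.897, a value that leaves out that the regions came from the same animals. In the PFC the count was 356 by DESeq2, 108 with 2 surrogate variables and 135, 25 and 24 within cohorts 1, 2 and 3, and without the XY-Sry control replicate 38 the count outside X and Y was 124. Within the cohorts, 107, 2 and 2 of the PFC genes lay outside X and Y. In the NAc it was 76 under the stricter filter and 39, 20 and 20 within the cohorts, of which 17, 0 and 3 lay outside X and Y. With the interferon score as a covariate, a fit chosen after the calls were seen, the counts were 55 in the PFC and 26 in the NAc, with 26 and 1 outside X and Y. That score contains called genes and itself differs between complements, so fewer calls follow by construction and point to no cause.

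Gonad type was compared as testes minus ovaries, a contrast that also carries the Sry transgene. In the PFC, edgeR called 9 genes. Of these, 6 belonged to the class I histocompatibility family, whose products present peptides to T cells, though H2-Q5 among them is annotated as a polymorphic pseudogene. No list of this class was fixed or tested. Each of the 6 was lower with testes. H2-K1 had 13.1 ± 2.17 CPM with testes (SD, n = 24) and 18.1 ± 6.41 with ovaries (SD, n = 24). It fell by 0.41 (SE 0.0820, edgeR adjusted p = 0.0259), H2-D1 by 0.34 (SE 0.0694) and H2-Q4 by 0.49 (SE 0.0932). Further members outside the naming rule, chosen after their values were seen, were H2-Q6 (ENSMUSG00000073409, chromosome 17) at -1.32 (SE 0.207, edgeR adjusted p = 0.001), H2-Q7 at -1.54 (SE 0.260) and H2-Q5 at -1.49 (SE 0.274). Levels of the last 2 were low. H2-Q7 had 0.157 ± 0.121 CPM with testes against 0.462 ± 0.358 with ovaries, and H2-Q5 0.0713 ± 0.0468 against 0.197 ± 0.107 (SD, n = 24 each). These genes are near-identical in parts, so reads can be shared among them and each value is uncertain. Fmo2, a flavin-containing monooxygenase, had 1.90 ± 0.390 against 2.63 ± 0.603 CPM (-0.44, SE 0.0732, edgeR adjusted p = 0.00183). Neu4, a sialidase found in oligodendrocyte precursors, had 5.30 ± 0.538 against 6.23 ± 0.556 CPM (-0.24, SE 0.0380, edgeR adjusted p = 0.001). The predicted gene Gm13091, also chosen afterwards, was the only one of the 9 called genes that was higher with testes (0.31, SE 0.0606). DESeq2 called 17 genes and limma-voom 14, and within cohorts 1, 2 and 3 edgeR called 0, 1 and 0.

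In the NAc, edgeR called 2 genes, both lower with testes and both chosen after their values were seen. H2-Q6 had 0.375 ± 0.802 CPM with testes and 1.14 ± 1.08 with ovaries (SD, n = 24 each), a log2 fold change of -1.79 (SE 0.331, edgeR adjusted p = 0.0459). Gm4951, an interferon-inducible GTPase, had 0.292 ± 0.670 against 1.16 ± 1.16 CPM (-2.12, SE 0.401, edgeR adjusted p = 0.0459). Values that did not pass were -0.23 for Ramp2, a receptor partner of vascular cells (edgeR adjusted p = 0.0547), -0.74 for H2-Q4 (0.0899), and -2.0 for Apol11b (0.126). Interferon-response genes lay lower with testes in 20 of 20 cases in each region, with medians of -0.24 in the PFC and -0.55 in the NAc. Over all genes edgeR called none of them, while adjusted over the list alone 9 and 19 were called. The camera calls of this list were lost with an estimated correlation (adjusted p = 0.239 in the PFC and 0.211 in the NAc), and the fry adjusted p was 0.202 and 0.039. The interferon score differed by -0.24 in the PFC (permutation p = 0.023, adjusted p = 0.069) and by -0.58 in the NAc (permutation p = 0.00466, adjusted p = 0.0186). It was -0.30, 0.14 and -0.42 within the 3 cohorts of the PFC and -0.71, -0.42 and -0.59 in the NAc. The count of 2 was 19 by DESeq2, 3 by limma-voom and 0 under the stricter filter. Without the XY-Sry control replicate 33 it was 68, of which 66 were lower with testes and 15 belonged to the interferon list. It ran from 0 to 6 without any other single library.

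Other lists had camera calls for gonads, none of which held with an estimated correlation. In the PFC, microglial markers were all lower with testes (14 of 14, median -0.09, 7 adjusted over the list alone), as were markers of meninges and fibroblasts (9 of 9, median -0.24) and of blood cells (6 of 6, median -0.36). With an estimated correlation these had adjusted p = 0.239, 0.239 and 0.240. The heat shock and unfolded protein list (median -0.05), the astrocyte list (-0.03) and the oligodendrocyte precursor list (-0.03) gave adjusted p = 0.239, 0.308 and 0.239 on the same basis. In the NAc, blood cell genes, such as the globin gene Hbb-bs at -0.47 (edgeR adjusted p = 0.354), had a median of -0.44 and microglial markers one of -0.11 (adjusted p = 0.270 and 0.687 with an estimated correlation).

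Stress did not bring any gene past the test in either region. In the PFC, the smallest adjusted p was that of Gabrg1, a GABA-A receptor subunit (log2 fold change -0.15, SE 0.0313, edgeR adjusted p = 0.207). It had 23.04 ± 1.38 CPM in stressed and 25.5 ± 1.68 in control mice (SD, n = 24 each). Next were Atp6v1g2, a subunit of the proton pump of vesicles (0.08, SE 0.0176), 4930467D21Rik (-0.89), Plcz1, a phospholipase (-0.58, SE 0.130), and Hcrtr2, an orexin receptor (0.31, SE 0.0716). In the NAc, the smallest p values belonged to Gm15246 (0.33, SE 0.0713, edgeR adjusted p = 0.692), which overlaps other genes of the distal X, and to Neat1. Neat1, the RNA that builds paraspeckles, had 79.1 ± 15.8 against 67.4 ± 16.4 CPM (0.39, SE 0.0887, edgeR adjusted p = 0.742). They were followed by A930004J17Rik at 0.20, Gm15538 at 0.81 and Gm26736 at -1.22. The edgeR count was 0 in each region, with 1105 of 19292 genes in the PFC and 903 of 19684 in the NAc at an unadjusted p under 0.05. With no effect, a share of about 0.05 of the tested genes would lie there, which holds for the later counts of this kind too. DESeq2 called 2 and limma-voom 5 in each. Without the PFC XX control replicate 29 the PFC count was 1.

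For stress over all genotypes, no list call held with an estimated correlation. All 18 members of the oligodendrocyte and myelin list were above 0 in both regions, with medians of 0.13 in the PFC and 0.14 in the NAc (camera adjusted p = 1.41e-05 and 1.38e-08). None passed alone, and the calls were lost with an estimated correlation (adjusted p = 0.777 and 0.649). In the PFC the myelin enzyme genes Fa2h and Aspa stood at 0.23 and 0.19, and the cytoskeletal gene Ermn at 0.26. Lower after stress in the PFC were the 12 blood vessel markers (median -0.07), 11 of 12 astrocyte markers (median -0.05) and the 6 blood cell genes (median -0.33), each with adjusted p = 0.615 with an estimated correlation. In the NAc, 56 of 68 nuclear genes of oxidative phosphorylation were lower (median -0.04; adjusted p = 0.649 with an estimated correlation), and heat shock genes had a median of -0.03 (0.649). Glucocorticoid-induced genes, which respond to stress hormones, had medians of -0.04 in both regions (camera adjusted p = 0.210 in the PFC and 0.115 in the NAc). Immediate early genes, which follow neuronal activity, had -0.02 and -0.04 (0.707 and 0.0579), and interferon genes in the PFC 0.06 (0.210). Stressed and control mice differed in interferon score by 0.04 in the PFC (permutation p = 0.759) and by -0.19 in the NAc (permutation p = 0.373). Within the cohorts the differences were -0.08, -0.23 and 0.37 in the PFC and -0.25, -0.52 and 0.43 in the NAc.

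Within single genotypes, stress again called no gene with edgeR. In the PFC of XY- mice, the smallest adjusted p values were 0.0581 by edgeR (n = 6 stressed and 7 controls). They belonged to Htra1, a secreted serine protease (-0.26, SE 0.0511), and Rilpl1, a regulator of ciliary transport (-0.25, SE 0.05). The counts at an unadjusted p under 0.05 were 582, 1119, 1762 and 1216 in the PFC and 756, 491, 876 and 1220 in the NAc for XX, XXSry, XY- and XY-Sry. DESeq2 called 15 and limma-voom 4 genes in the PFC of XY- mice, limma-voom called 8 in the NAc of XY-Sry mice, and both called 0 elsewhere. Without the PFC XY- stress replicate 32 edgeR called 6 genes in XY- mice, and 15 other left-out libraries gave 1 to 5. The genes with the smallest p in the other genotypes in the PFC were Six4 (-0.77) and Stmnd1 in XX, and Foxs1 (-1.55) and Cd24a (-0.54) in XXSry mice. In XY-Sry mice they were Tmem245 (-0.18, SE 0.0389) and Nyap2 (-0.24, SE 0.0533). In the NAc they were B230110C06Rik and Acat3 (0.50) in XX, Scube2 (1.12) in XXSry, Gm26736 and C1rl (1.60) in XY-, and Gm15538 and Veph1 (-1.61) in XY-Sry mice, with edgeR adjusted p of at least 0.527.

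Some gene lists had camera calls for stress within single genotypes, although each such call was lost with an estimated correlation and with fry. In the PFC of XY-Sry mice, all 18 myelin genes (median 0.33) and all 68 nuclear genes of oxidative phosphorylation (median 0.07) were higher after stress and all 9 meningeal markers lower (median -0.44). With an estimated correlation these had adjusted p = 0.223, 0.190 and 0.223. In XX mice, immediate early genes had medians of -0.18 in the PFC (19 of 22 lower; adjusted p = 0.314 with an estimated correlation) and -0.16 in the NAc (18 of 22; 0.581), beside meningeal markers at 0.33 in the PFC. In XXSry mice, all 14 microglial markers were lower in the PFC (median -0.17; adjusted p = 0.454 with an estimated correlation) and all 18 myelin genes higher in the NAc (median 0.23; 0.815). In XY- mice, glucocorticoid-induced genes had medians of -0.21 in the PFC (15 of 20 lower; adjusted p = 0.375 with an estimated correlation) and -0.22 in the NAc (16 of 20; 0.299), and all 20 interferon genes were higher in the PFC (median 0.48; 0.375). Without the 2 XY- controls of cohort 3, replicates 16 and 19, a fit chosen after the data were seen, the glucocorticoid medians were -0.02 and 0.05 and the interferon median was 0.28, while in cohort 1 alone the interferon median was -0.15. In the NAc the interferon median of 0.235 was -0.115 without these controls and -0.753 in cohort 1. In the PFC, the XY- stress replicate 32 of cohort 3 had an interferon score of 3.78, against 2.04 to 2.43 in the others of its group. Striatal neuron markers had NAc medians of -0.29 in XY- and 0.30 in XY-Sry mice (camera adjusted p = 0.422 and 0.858 with an estimated correlation). For the mitochondrial genome list in the PFC of XXSry and XY- mice the test and median were negative (-0.13 and -0.11) and the mean positive (0.21 and 0.12).

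Tests of the differences between these effects found no gene either. For stress by chromosome complement, edgeR called 0 genes in each region (606 in the PFC and 594 in the NAc at an unadjusted p under 0.05). It also called 0 for stress by gonads (1296 and 578) and for chromosome complement by gonads (839 and 559). DESeq2 called 6 genes for stress by gonads and 1 for chromosome complement by gonads in the PFC and 0 in the other tests, and limma-voom 0 in all. The smallest adjusted p, 0.0931 by edgeR, belonged to Arl4d, a small GTPase gene (0.49, SE 0.0973), and Scgn, a calcium-binding protein gene whose fitted value is not given, as its mean was -2.32 log2 CPM. Both were for stress by gonads in the PFC, where the count was 2 without the XY- stress replicate 41 or the XY-Sry control replicate 46, and 1 without the XY-Sry stress replicate 8 or the XY- control replicates 13 and 19. The other genes with the smallest p were Pkd2l1 and Cacna2d2 (-0.21) for stress by chromosome complement and Gm42735 (0.65) and Ky (-0.67) for chromosome complement by gonads in the PFC. In the NAc they were Sumo2 (0.28) and Cyp26b1 (-1.33), Myom1 (-0.60) and Bcl7b (0.22), and Mmrn2 (0.51) and Klf10 (-0.66), in the same order of tests, with edgeR adjusted p of at least 0.987. Across genes, which are not independent replicates, the stress effects of pairs of genotypes had a mean correlation of 0.0439 in the PFC and 0.0590 in the NAc. Simulated sets with no effect, 20 in number, gave 0.0443 to 0.0662 and 0.0404 to 0.0657. Each gene was drawn independently in them, so the simulated ranges leave out correlation between genes. They therefore cannot show that a pair of genotypes stands apart. Single pairs in the PFC ran from -0.0400 for XY- with XY-Sry (simulated 0.0384 to 0.0933) to 0.221 for XXSry with XY-Sry mice (simulated 0.0369 to 0.107). The latter was 0.178 with no cohort term (simulated -0.0476 to 0.0201) and 0.167 in cohort 1 (simulated -0.0217 to 0.0258), which held 1 XY-Sry control. The pair of XY- with XY-Sry was -0.1424 (simulated -0.0263 to 0.0261) and -0.1275 (simulated -0.0348 to 0.0381) in these settings. In the NAc they ran from -0.0113 for XY- with XY-Sry (simulated 0.0428 to 0.0921) to 0.127 for XXSry with XY- mice (simulated 0.0264 to 0.0707).

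**Figure D3:**
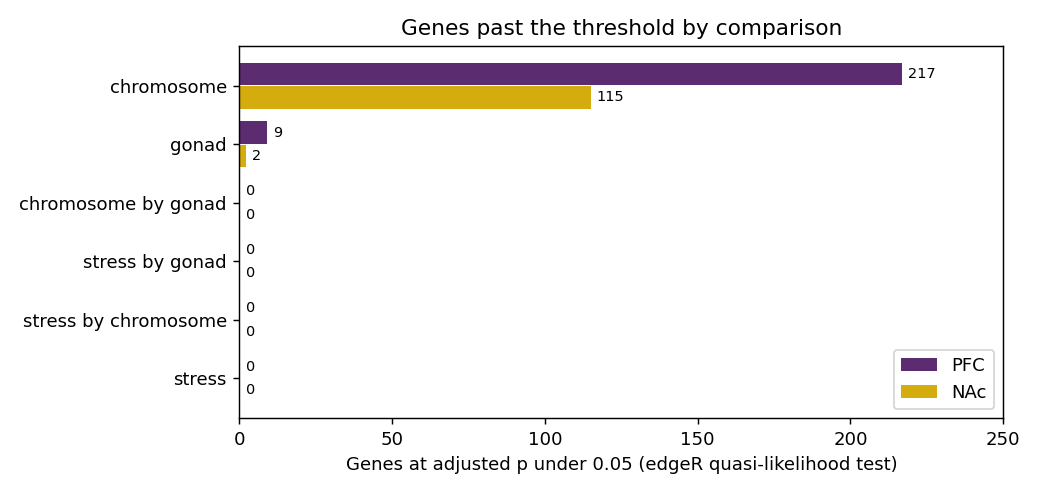
Horizontal bars, starting at 0, give the number of genes that edgeR called at an adjusted p under 0.05 for each comparison in the PFC and the NAc. Chromosome complement has the longest bars, with 217 and 115 genes, gonads have 9 and 2, and stress and the interactions 0.

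Markers of striatal and cortical neurons differed between the regions. CPM of each region are scaled within that region, while log2 fold changes come from a fit that scales both regions together. Compared in the same animals, Drd1 and Drd2, the dopamine receptor genes of striatal projection neurons, had 247.9 ± 39.4 and 80.7 ± 17.3 CPM in the NAc against 8.85 ± 1.45 and 0.679 ± 0.364 CPM in the PFC (SD, n = 48 each). Their log2 fold changes were 4.63 (SE 0.0490) and 6.86 (SE 0.0901). Penk, which encodes enkephalins, was 5.14 higher (SE 0.0618), the adenosine receptor gene Adora2a 6.20 (SE 0.0832) and the dopamine-regulated phosphatase inhibitor Ppp1r1b 4.17 (SE 0.0563). Tac1, the substance P gene, was higher by 4.21 (SE 0.0673) and adenylyl cyclase Adcy5 2.30 (SE 0.0419). Slc17a7, the vesicular glutamate transporter of cortical neurons, had 303.5 ± 159 CPM in the NAc and 1434 ± 75.9 in the PFC (-2.59, SE 0.169). Cux2, an upper-layer transcription factor, had 24.5 ± 4.78 and 136.7 ± 10.8 CPM (-2.62, SE 0.0477), and Nrn1, Emx1, Mef2c and Rorb differed by -3.71, -3.44, -2.64 and -0.60. All 15 striatal markers were higher in the NAc (median 4.21) and all 12 cortical ones higher in the PFC (median -2.63). Of 10 genes on the interneuron list, edgeR called 5 higher in each region, but the direction of Sst, counted with the PFC, depended on the scaling. Gad1 and Gad2, the GABA-synthesising enzymes, were higher by 1.06 (SE 0.0277) and 2.14 (SE 0.0382) in the NAc, and the GABA transporter gene Slc32a1 by 1.53 (SE 0.0407). These genes serve GABA neurons of any kind, so the even split does not describe interneurons alone. Calb2 and Lhx6 were also higher in the NAc, by 0.93 and 0.31, while Pvalb differed by -2.06 (SE 0.128) and Vip by -2.79 (SE 0.0990). Sst stood at -0.10 in the joint fit (SE 0.0344, edgeR adjusted p = 0.00921), with 140.9 ± 20.5 CPM in the NAc and 137.4 ± 12 in the PFC when scaled within each region. Septal and hypothalamic markers, of neighbouring tissue, were higher in the NAc for 8 of 10 members, Zic1 by 1.46 (SE 0.105), which is uncertain because Zic4 overlaps it on the opposite strand. Among the 8, Ghrh, Pmch and Gal had only 0.111, 0.282 and 0.301 CPM in the NAc, so the count alone does not show that such tissue was included. With the animal as a block, edgeR called 17113 genes, 8770 higher in the NAc and 8343 in the PFC, and 15838 in cohort 1 alone. Joint-fit values lay below the ratios of the separately scaled CPM for other genes too. Npy, for example, stood at -0.24 with 47.3 ± 7.58 CPM in the NAc and 50.9 ± 5.51 in the PFC. The direction of small differences, and with it this split, thus depends on the scaling. Adjusted over the list alone, the striatal, cortical and interneuron counts were 15, 12 and 10.

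**Figure D4:**
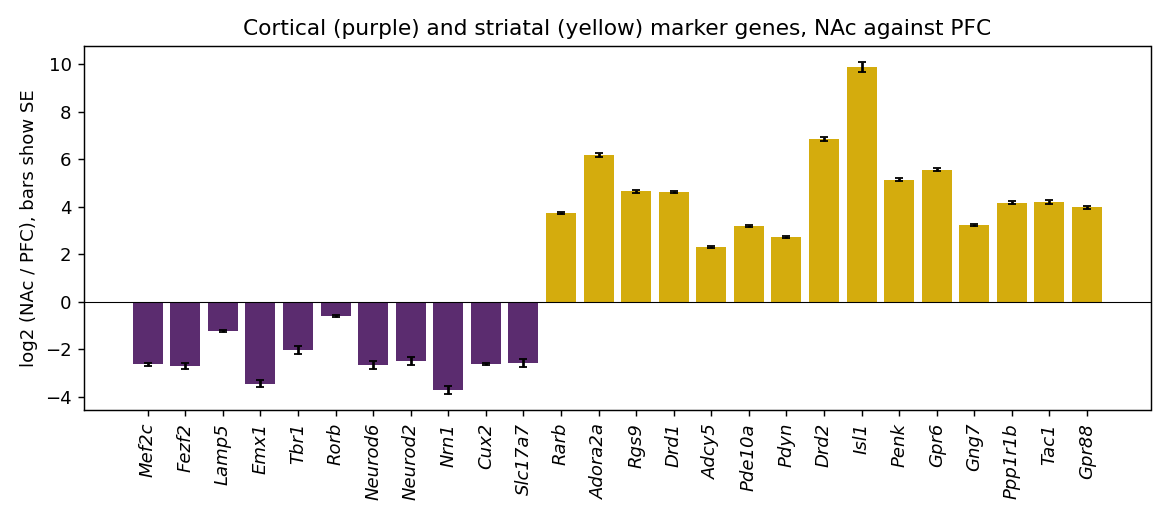
Log2 fold change of the NAc over the PFC, with SE, for 11 cortical excitatory and 15 striatal projection neuron markers in 48 animals; the bar of Isl1 is a fitted value for a gene near 0 counts in the PFC. All cortical markers shown lie below 0 and all striatal markers above it.

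Whether stress, chromosomes or gonads acted differently in the regions was tested by interaction with region. For chromosome complement, edgeR called 3 genes, Eif2s3y, Xist and Ust. The counts of Eif2s3y in XX and of Xist in XY mice were near 0, so their fitted values are not given. Ust encodes a sulfotransferase of proteoglycans (ENSMUSG00000047712, chromosome 10, 8204756 to 8518825). Its XX minus XY difference was 0.29 higher in the NAc than in the PFC (SE 0.0569, edgeR adjusted p = 0.0451). With no block for the animal this count was 0, and in cohort 1 it was 2. For stress and gonads, edgeR, the only tool run, called 0 genes, with 989 and 1046 at an unadjusted p under 0.05. The smallest p were those of 4930470G03Rik (1.24) and Rangrf (-0.32) for stress and Gm12525 (1.05) and Inip (0.15) for gonads. The stress effects in the PFC and NAc had a correlation of 0.0810 across genes, which are not independent replicates, and 18 of 50 splits of the animals gave as large a value.

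The cohorts, a batch label, differed in the PFC by 35 genes with edgeR (186 by DESeq2 and 15 by limma-voom) and in the NAc by 0 (1080 at an unadjusted p under 0.05; 1 by DESeq2 and 1 by limma-voom). The PFC count ran from 3 without the XY-Sry control replicate 46 to 59 without the XY-Sry stress replicate 23. No XX or XXSry control came from cohort 3 and no XXSry or XY- stressed mouse from cohort 2, so there these cohorts hold a single treatment.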

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

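The test of whether a few animals carried the interferon difference and the interaction of chromosome complement with gonads on the interferon score were chosen only after the result was seen, as were the fits with the interferon score as a covariate. Of 112 tests, 7 measures in each of 16 groups of libraries, 10 found a library that stood apart from its group, where chance gives about 1 in 20.

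The interferon score of the PFC XY- stress replicate 32 was 3.78, against 2.04 to 2.43 in the other 5 libraries of its group. In the NAc, the XY-Sry control replicate 33 had an interferon score of 3.97 against 1.58 to 2.28, and the XY-Sry stress replicate 7 had 2.31 against 1.77 to 1.88. The cortical neuron score was 6.96 in the PFC XY- control replicate 13 (others 7.02 to 7.06) and 2.47 in the NAc XXSry control replicate 27 (others 4.21 to 5.21). The blood cell score was 1.45 in the PFC XY-Sry stress replicate 49 (others 2.91 to 3.62), and the ependyma score was -0.98 in the NAc XX stress replicate 25 (others 0.73 to 1.68). Total counts stood apart in the PFC XX stress replicate 20 at 89.5 M (others 68.5 to 75.4). They did so too in the PFC XY-Sry control replicate 33 at 67.6 M (others 83.3 to 88.8), and in the NAc XY-Sry control replicate 47 at 106.1 M (others 70.2 to 82.0). Between regions, chromosome complement differed in effect for 3 genes, of which Eif2s3y and Xist rest on counts near 0 in 1 complement, and for 0 with no block for the animal. In the NAc, the gonad effect on the interferon score was -0.25 in XX and -0.91 in XY mice, a difference of 0.66 (permutation p = 0.032, adjusted p = 0.0641 over 2 tests). The PFC difference was 0.21 (permutation p = 0.269).

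Interferon-response genes were lower in XX than in XY mice, with list medians of -0.51 in the PFC and -0.87 in the NAc. More microglia in XY mice would lower their markers in XX by about as much, but the microglial medians were only -0.11 (SE over 14 markers 0.0253) and -0.079 (SE 0.0299). That SE covers the spread between markers, not between animals. A few animals with high scores would leave the group medians alike, but the medians also differed (permutation p = 4e-05 in the PFC and 0.00024 in the NAc), and an effect of the cohorts would vanish within them, while the within-cohort differences nearest to 0 were -0.35 in the PFC and -0.76 in the NAc. These values argue against each of the 3 as the whole cause, so a biological hypothesis may be stated, found on these data and not itself tested: the level could follow the extra dose of Tlr7 and its neighbours, or another gene of the Y- chromosome. Every XY mouse carried both, so these stay open, as does the breeding background of the genotypes. The 2 XY genotypes differed in score all the same, with means of 2.91 in XY- and 2.09 in XY-Sry mice in the NAc and 2.25 and 1.93 in the PFC. In the NAc, XX mice had 1.84 and XXSry mice 1.60, and the XY-Sry mean includes replicate 33 at 3.97. A dose that both XY genotypes shared would not by itself set them apart.

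Actb was lower in XX than in XY mice, by 0.18 in the PFC and 0.13 in the NAc, and Actg1 was called lower in the PFC alone (-0.08 in the NAc, edgeR adjusted p = 0.918). One candidate explanation is the dose of Tmsb4x, which binds actin monomers that hold back a cofactor of serum response factor; among measured targets of that factor, 19 of 23 lay lower in XX in the PFC (median -0.09, p = 0.00264 with an estimated correlation) and 14 of 23 in the NAc (median -0.03, p = 0.433). Several of those targets are also expressed by vessel and meningeal cells, whose markers had PFC medians of -0.0693 (SE over 12 markers 0.0132) and -0.24 (SE over 9 markers 0.0417). Actb is abundant in every cell type, so tissue makeup and Tmsb4x dose cannot be told apart from these values.

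H2-Q6, a class I gene, was lower with testes at -1.32 in the PFC and -1.79 in the NAc, while H2-Q4, H2-Q5 and H2-Q7 of its cluster were called in the PFC alone (NAc edgeR adjusted p = 0.0899, 0.339 and 0.126). With the interferon score as a covariate, H2-Q6 was at -1.02 in the PFC (SE 0.167, edgeR adjusted p = 0.00389). In the NAc, H2-Q6 moved from -1.79 (SE 0.331) to -0.95 (SE 0.188, edgeR adjusted p = 0.0907). The difference shrank there and its SE nearly as much, so that a call close to the threshold ended. The rule fixed for this test asked for a call in both regions to set the interferon level aside, so it decided nothing. For the PFC alone, the score did not account for the whole difference, though a mean of 20 genes need not hold the whole interferon level. Whether the interferon level accounts for part of the NAc difference stays open. A single library does not carry the PFC call, which passed without each of 48 libraries. The NAc call passed without only 20 of 48, with edgeR adjusted p up to 0.108 without the XXSry stress replicate 21. Its log2 fold change stayed between -2.245 and -1.682 over these 48 fits. Single libraries thus moved a call close to the threshold across it, and not the direction. Reads shared within the cluster, a strain variant near it and the Sry transgene itself stay open, as untested.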

How the results depend on the processing

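The fits with marker scores, with the interferon score, without 2 cohort 3 XY- controls and without single animals in the region comparison were chosen only after the result was seen. Directions and sides of the threshold mostly held, over called and uncalled genes together. Of the values of single genes under the alternatives fixed beforehand, left-out libraries aside, 8029 kept both, 187 lost and 58 gained significance. Another 450 changed direction while called in neither fit, and 1 reversed, changing direction with a call in at least 1 fit. With libraries left out the numbers were 37527, 255, 102 and 79 in the same order, with none reversed. DESeq2 size factors, no filter and the additive model left the counts of genes within 1.5 times. The exception was 3 genes for stress in XY- mice in the PFC with the size factors. The reversed values were Gja1 for chromosomes in the PFC in cohort 3 alone (0.0317) and, for chromosomes in the NAc with the interferon score as a covariate, Oasl2 (0.0752) and Irf7 (0.103), which that covariate contains. Smaller cohorts have fewer samples; for the other changes the cause was not tested.

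For chromosome complement in the PFC, the count of 217 genes was 356 by DESeq2, 108 with 2 surrogate variables, 135, 25 and 24 in cohorts 1, 2 and 3, 122 with marker scores and 55 with the interferon score. Outside X and Y, 188 became 320, 81, 107, 2, 2, 94 and 26 in the same order, and ran from 124 (without the XY-Sry control replicate 38) to 259 with single libraries left out. In the NAc, 115 was 76 under the stricter filter, 39, 20 and 20 in the cohorts and 26 with the interferon score, and outside X and Y 87 became 52, 17, 0, 3 and 1.

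For gonads in the PFC, the count of 9 was 17 by DESeq2, 14 by limma-voom, 0, 1 and 0 in the cohorts and 15 without the 2 XY- controls. In the NAc, the count of 2 was 19 by DESeq2, 5 without the 2 XY- controls, and 0 under the stricter filter, with surrogate variables, in cohorts 2 and 3, with marker scores and with the interferon score. With single libraries left out it ran from 0 to 68. It was 68 without the XY-Sry control replicate 33, 6 without the XY- stress replicate 15, and 4 without the XY- control replicate 16. It was 1 without the XXSry control replicate 11, the XY- stress replicate 14 or the XY-Sry stress replicate 30, and 0 without each of 28 others.

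For stress in the PFC, the count of 0 was 1 with no cohort term, in cohort 2, with marker scores and without the 2 XY- controls, 2 by DESeq2 and 5 by limma-voom, and 0 to 1 with libraries left out (1 without the XX control replicate 29). In the NAc it was 2 by DESeq2, 5 by limma-voom and 1 without the 2 XY- controls. For stress in XY- mice in the PFC, the count of 0 was 3 with DESeq2 size factors, 5 under the stricter filter, 15 by DESeq2, 4 by limma-voom, 4 with marker scores and 0 to 6 with libraries left out. In the NAc it was 0 to 1 (1 without the XY- stress replicate 15). For stress in XY-Sry mice in the NAc it was 8 by limma-voom, 1 with marker scores and 0 to 2 with libraries left out (2 without the XY-Sry stress replicate 8). For stress by gonads in the PFC it was 6 by DESeq2 and 0 to 2 with libraries left out, and for chromosomes by gonads 1 by DESeq2. The 35 cohort genes of the PFC were 186 by DESeq2, 15 by limma-voom and 3 to 59 with libraries left out, and the NAc count of 0 was 1 by DESeq2 and by limma-voom.

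Of 406 list tests, 100 were called with the preset correlation, 8 with an estimated one and 9 by fry. The mean correlation of stress effects between genotypes, 0.0514 over both regions, was 0.00324 with no cohort term (-0.00568 in the PFC, simulated -0.0247 to 0.0126, and 0.0122 in the NAc, simulated -0.0148 to 0.0147). It was 0.0138 in cohort 1 alone (-0.0193, simulated -0.0157 to 0.0203, and 0.0470, simulated -0.0133 to 0.00721), where XY-Sry mice had 1 control, assumed to vary like the other groups. The simulated means with no effect also moved, from 0.0557 and 0.0583 to -0.000731 and -0.00176 with no cohort term. The simulated genes were drawn independently, so these ranges do not cover correlation between genes. With no block for the animal, the count of genes whose chromosome effect differed by region went from 3 to 0. The other calls of the region comparison were not all compared gene by gene with and without the block. At these library sizes, 82.1% of simulated 1.2-fold changes were recovered for stress over all genotypes in the PFC and 67.2% in the NAc, and 49.3% and 17.9% for stress in XX mice; depth itself was not varied.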

Other observations

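The correlation of interferon scores between regions, pooled and within genotypes, was chosen as a test only after the result was seen, as were the correlations of components with list scores, the fits without 2 cohort 3 XY- controls and the splits that leave out sex-linked lists or count region by chromosome genes outside X and Y.

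Single genes of other lists also differed between chromosome complements in the PFC. Of 14 microglial markers, 3 fell in XX, and 7 did adjusted over the list alone. The protease gene Ctss had 52.7 ± 3.36 CPM in XX (SD, n = 23) and 68.3 ± 17.1 in XY mice (SD, n = 25), a log2 fold change of -0.34 (SE 0.0648, edgeR adjusted p = 0.00249). Siglech, a sialic acid-binding receptor, fell by 0.20 (SE 0.0413) and the complement gene C1qc by 0.20 (SE 0.0519). Gja1, the gap junction protein of astrocytes, fell by 0.10 (SE 0.0263, edgeR adjusted p = 0.0425), the dopamine receptor gene Drd2 by 0.65, and Rps4l, a transcribed pseudogene that shares sequence with ribosomal genes and is therefore uncertain, by 0.32. Adcyap1, a neuropeptide gene, rose by 0.21. Globin and other blood cell genes lay lower in XX in 6 of 6 cases in each region, with medians of -0.35 and -0.29 (adjusted p = 0.358 and 0.181 with an estimated correlation). Heat shock genes were slightly higher (17 of 19, median 0.05 in the PFC; adjusted p = 0.262 with an estimated correlation). Cytosolic ribosomal genes were slightly lower (72 of 85, median -0.03; 0.364), as were glucocorticoid-induced genes (15 of 20, median -0.07; 0.364). In the NAc, striatal neuron markers lay higher in XX for 14 of 15 members (median 0.10; adjusted p = 0.518 with an estimated correlation).

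Beyond neurons, all 18 oligodendrocyte and myelin genes were higher in the NAc than in the PFC (median log2 fold change 2.25), as were all 6 ependymal markers (1.89), 7 of 10 choroid plexus markers (1.60) and 71 of 85 cytosolic ribosomal genes (0.35). Higher in the PFC were all 9 markers of meninges and fibroblasts (median -1.58), all 6 blood cell genes (-1.05), 19 of 22 immediate early genes (-0.66), 14 of 22 glutamate receptor genes (-0.50) and 8 of 12 astrocyte markers. Neuropeptide genes were divided, with 14 of 26 higher in the NAc and 11 in the PFC, as were monoamine genes (10 and 11 of 23), circadian genes (7 and 8 of 16), steroid receptor genes (6 and 7 of 14) and GABA receptor genes (7 and 7 of 15). These counts are edgeR calls with the animal as a block. The direction of small differences among them depends on how the regions are scaled to each other.

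If the interferon level were a property of the animal, scores in the PFC and NAc would go together within a chromosome complement. In XY mice Pearson's r was 0.451 (n = 25, permutation p = 0.0148) and Spearman's rho 0.778 (permutation p = 2e-05, the smallest the draws can give). Without the 2 animals farthest from the median r was 0.759, and within the cohorts it was 0.772, 0.840 and 0.400 (n = 9, 7 and 9). In XX mice r was 0.222 (n = 23, permutation p = 0.309) and rho 0.301 (p = 0.162), 0.227 without the 2 farthest animals and 0.220 in cohort 1 (n = 14), with too few animals in cohorts 2 and 3. The pooled XY value also carries the difference between the means of XY- and XY-Sry mice. Within genotypes, the 2 farthest animals left out were those farthest from the median PFC score, whatever their NAc score. There, r was 0.843 in XY-Sry (n = 12, permutation p = 4e-05, adjusted p = 0.00016 over 4 tests; rho 0.895, permutation p = 0.00017) and 0.738 without the 2 farthest animals. It was 0.131 in XY- (n = 13, permutation p = 0.691, adjusted p = 0.757; rho 0.511, permutation p = 0.0774), 0.585 without the 2 farthest animals and 0.613 in cohort 1. In XX and XXSry mice it was 0.102 and 0.148 (permutation p = 0.757 and 0.645, adjusted p = 0.757 each; rho 0.109 and 0.14, permutation p = 0.755 and 0.668), and -0.0144 and 0.245 without the 2 farthest animals. Cohort 1 gave 0.233 in XXSry mice (n = 9) and held too few XX and XY-Sry animals. The hypothesis may hold in XY-Sry mice and stays open in the others; whether the genotypes differ in r was not tested.

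The glucocorticoid-induced list in stressed XY- mice (medians -0.21 in the PFC and -0.22 in the NAc) rested on controls. Without the XY- control replicates 16 and 19, whose scores were 4.40 and 4.25 in the PFC, the medians were -0.02 and 0.05, and in cohort 1 alone -0.01 and 0.01. The interferon median of 0.48 in the PFC was 0.28 without these controls and -0.15 in cohort 1. That of 0.235 in the NAc was -0.115 and -0.753 in the same order. Among stressed mice, the PFC XY- replicate 32 had an interferon score of 3.78, against 2.04 to 2.43 in the others of its group. It lies outside cohort 1, so the cohort 1 value leaves it out as well as these controls. How far this library carried the PFC median was not tested.

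Other splits of the libraries tested whether chance could give as many calls. For chromosome complement, no other of 100 splits reached the real 217 genes in the PFC (highest other 82) or 115 in the NAc (highest other 1). Nor did one reach the 188 and 87 outside X and Y (78 and 1), so that 1 of 100, the real one, was as large. For gonads, 1 of 100 splits reached the 9 genes of the PFC (highest other 5) and 3 of 100 the 2 genes of the NAc (highest other 612). For the cohorts, 2 of 100 reached the 35 cohort genes of the PFC (highest other 344). The 17113 genes between regions were reached by 1 of 25 splits, the real one (highest other 13778). The 217 and 115 genes include X and Y genes, which follow the real label alone, so the counts outside X and Y bear on chance there. For those, the PFC gonad genes and the regions, chance can be excluded at a share of 0.05 per test, uncorrected over tests. The gonad splits redrew whole genotypes, so the chromosome effect added to their spread. The 2 gonad genes of the NAc stay open, as their count ran from 0 to 68 with single libraries left out. So do the 35 cohort genes of the PFC, whose count ran from 3 to 59 in the same way. The 3 genes of region by chromosome complement were reached by 1 of 25 splits (highest other 1), but Eif2s3y and Xist among them follow the real label alone. Outside X and Y, 2 of 25 splits reached the real count of 1 (highest other 1), which does not exclude chance. Where the real count was 0, every split reaches it by construction (100 of 100, or 25 of 25 for region by stress and region by gonads, with a highest other of 1 each), so that the test says nothing there. The highest others were then 195 for stress, 1 for stress by chromosomes, 265 for stress by gonads, 4 for chromosomes by gonads, and 3, 621, 33 and 1 for stress in XX, XXSry, XY- and XY-Sry mice in the PFC. In the NAc they were 1, 624, 62, 2850, 1205, 2, 0 and 432 in that order, and 601 for the cohorts. Single splits called several times the real number of genes for gonads in the NAc (612 against 2) and cohorts in the PFC (344 against 35), and up to 2850 beside a count of 0 (chromosomes by gonads in the NAc), which points to a structure of the samples. Component 1 of the NAc libraries (8.55% of the variance) went with the ependyma score (r = -0.876, rho = -0.866, n = 48) and component 2 (7.93%) with the cortical neuron score (r = -0.888, rho = -0.895). Each r and rho had a permutation p of 1e-05, the smallest the draws can give (adjusted p = 0.000211 for r over 232 tests). Without the 2 farthest libraries r was -0.854 and -0.871, and within cohorts 1, 2 and 3 it was -0.87, -0.881 and -0.889, and -0.911, -0.887 and -0.887. In the PFC, component 1 (5.93%) went with the score of meninges and fibroblasts (r = 0.855, rho = 0.776, with the same p values), at 0.806 without the 2 farthest libraries and 0.879, 0.942 and 0.608 within the cohorts. Whether the splits with many calls follow these components was not tested.

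For gene lists, 4 of 100 splits called as many as the 15 lists of chromosome complement in the PFC (highest other 17) and 12 of 100 as many as the 11 in the NAc (highest other 16). These counts include sex-linked lists, which follow the real label alone. Without those lists, 12 of 100 splits reached the real 11 in the PFC (highest other 15) and 37 of 100 the real 7 in the NAc (highest other 12). The list counts for gonads were reached by 23 splits in the PFC (10 lists, highest other 14) and 86 in the NAc (4, highest other 14), and those for stress by 81 (4, highest other 11) and 96 (3, highest other 14). For stress in XX, XXSry, XY- and XY-Sry mice, 15, 21, 37 and 23 splits in the PFC reached the 7, 7, 9 and 9 lists called (highest others 9, 13, 12 and 12). In the NAc, 80, 57, 56 and 77 splits reached the 4, 5, 8 and 4 lists called (highest others 14, 10, 14 and 12). The correlation of stress effects between regions, 0.0810, was reached by 18 of 50 splits (highest other 0.166). Chance was not excluded for these.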
